A study of Homo sapiens and Mus musculus with 76 samples.

How the data were processed

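The series holds 76 sequencing libraries of polyadenylated RNA, 63 human and 13 mouse, in 15 groups set by the labels. For each library there is 1 deposited table of genes with 2 columns, reads per gene and RPKM. Per the file headers the first column holds the count of reads per gene, and the values were whole numbers. The RPKM column was made by the authors from these reads; the transcript length and the read total behind it are not given in the sources used here. Per the submitters' processing notes reads were aligned with STAR, whose version is not given, to hg19 for human and mm10 for mouse, and per the file headers genes follow RefSeq. The counting tool, its rule for reads with several matches and the strand setting are not given in the sources used here. MRPS18B, ABCF1, LSM2, PPT2 and a few other genes had RPKM values that imply a length of a few bases, HSPA1A and HLA genes had values that imply lengths well short of their transcripts, and up to 8 gene entries of a library had reads and an RPKM of 0, so counts were used throughout and RPKM only as an alternative.

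Human files had 24249 entries for 23571 symbols and mouse files 23827 entries for 23351 symbols, and entries of the same symbol were summed. They held at most 0.192% of the reads of a library. Library depth is the sum of reads over genes. No pair of libraries of a group was a copy of another, the lowest mean chi-square per gene between 2 of them being 1.81. That pair was HEK_100cells replicates 1 and 2, while replicate 3 had 20.8 and 20.5 with them. Replicates 1 and 2 thus differed by little more than counting error and may not be independent. The reads were amplified by PCR and carry no molecular identifiers, so intervals and floors cover counting error only.

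The groups, comparisons, tests, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined. In the input series, made of HEK293T RNA and pooled cells, genes were tested with the edgeR 4.0.16 quasi-likelihood F test on counts, with TMM factors and the filter filterByExpr, in R 4.3.3. Only the groups compared entered each fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. All tests were two-sided. The labels name no cultures for the replicates, so these p-values measure the spread between these libraries, which may be technical. The 6 comparisons were 100 cells with 1 ng of RNA, 10 cells with 100 pg, 100 with 10 cells, 100 with 50 cells, 1 ng with 100 pg and 1 ng with 10 pg, beside an interaction of source (cells or RNA) and input.

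A total of 26 gene lists was fixed: ribosomal protein, histone, nuclear oxidative phosphorylation, mitochondrially encoded, small nucleolar RNA, nuclear long non-coding RNA, small nucleolar RNA host, G1/S, G2/M, immediate early, heat shock, endoplasmic reticulum stress, cholesterol, glycolysis, kidney and neural, B cell, MHC class II, MHC class I, myogenic, fibroblast and matrix, contractile, macrophage, endothelial, epithelial, neuronal and T cell genes. Lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and, beside it, an estimated correlation, adjusted over the lists of a comparison, and with fry. None of the calls at the preset correlation held with an estimated one.

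Each single-cell group counts as 1 sample, because the labels name no culture behind the cells. No p-value, standard error or count of changed genes was therefore made for single cells. Levels are reads summed over the cells of a group as CPM, reads per 1000000 gene reads, with exact 95% Poisson intervals, and ratios have 1 CPM added to both groups. Where a group had 0 reads, a bound was computed against 3 reads over the group in place of the ratio, and in medians of lists such genes enter with 1 CPM added. A list's median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of expression. These lists held unrelated genes and were not matched on GC content or transcript length. Genes detected were counted after thinning to 1.8 M gene reads (1 M being 1000000) in the input series, 5 M in HEK293T single cells, 2 M for DG-75 against HEK293T and 3 M in mouse cells. Differences in detection in the input series were tested with exact permutation tests over 15 pairs of groups. Spread between libraries was the SD of log2(CPM + 1).

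Named genes of a tested comparison were taken from the 8 with the largest absolute log2 fold change in each direction among genes that passed, whose groups did not overlap and whose mean was at least 20 CPM in the higher group. For each described list genes were added from the 2 members with the smallest adjusted p in each direction, or the 2 with the highest mean where none passed. In single-cell comparisons they were taken from the 8 with the largest log2 ratio in each direction among genes with a read in all cells of the higher group, or all but 1, and at least 50 CPM there, and for each list the 2 with the largest ratio in each direction. XIST and Y-linked genes were left out. PDCD4 falls outside the rule.

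Transcript length and GC content came from the transcripts of GENCODE release 29, matched by RefSeq accession or else by symbol, for 23017 human symbols. The trend with both was removed, as an alternative chosen after seeing the data, by offsets in place of TMM factors. The offset of a library was the median deviation from the gene means in a grid of 10 by 10 bins, where bins with fewer than 20 genes took the median of all genes. Replicate numbers were checked for pairing by correlating, over genes, the deviations of libraries from their group means. Libraries numbered 2 and 3 resembled those of the same number between 100 and 50 cells (0.31, 0.73 and 0.82 for numbers 1 to 3) and between 100 and 10 cells (0.15, 0.45 and 0.59). Those numbered 1 resembled another number more (0.65 and 0.42). There was no such likeness between cells and RNA (0.04, 0.06 and 0.01 for 100 cells and 1 ng). The number was also fitted as a block.

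Alternatives were DESeq2 1.42.0, relative log expression factors, no filter on low counts and a filter at 10 CPM, limma on log2(RPKM + 1), all 6 input groups in 1 fit, the replicate block, and leaving out each library in turn. For values without a test they were other detection thresholds, depths and pseudocounts, RPKM, equal weights of cells, and leaving out cells. Alternatives chosen after seeing the data were library totals without factors, fits without CASC5, PDCD4 and CHMP4B (in mouse without Rn45s), removal of the length and GC trend with and without the block, the libraries of the block fit without a block, and leaving out Smart-Seq2 and variant cells. Other splits of the libraries were counted for every tested comparison of at least 3 libraries a group.

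The tests were tried on simulated data with 200 genes changed 2-fold or 4-fold at the depth of each comparison. Both groups had the same mean profile, apart from the changed genes, and the same fitted dispersion per gene. Groups of unlike spread, such as 1 ng and 10 pg, were thus not mimicked. Changes of 2-fold were recovered in 62.6% of genes for 100 cells against 1 ng, 35.4% for 10 cells against 100 pg, 57% for 100 against 10 cells, 35.4% for 100 against 50 cells, 36.4% for 1 ng against 100 pg and 0% for 1 ng against 10 pg. Changes of 4-fold were recovered in 97%, 77.6%, 94.9%, 99%, 76% and 0%. Genes not changed made up 8.62%, 4.35%, 10.2%, 8.22% and 5.08% of the calls in the first 5. In the single-cell simulation counts were drawn with counting error alone, without spread between cells. The median absolute log2 ratio was 0.967 for 2-fold and 1.94 for 4-fold changes, and 94% of the counting intervals held the true fold. A share near 95% was fixed by this design, so it does not show how the intervals do with real cells. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.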

Results

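The series measured polyadenylated RNA by sequencing full-length cDNA. The cDNA was made with Smart-Seq2 or with SMART-Seq, protocols in which reverse transcriptase switches templates at the end of an RNA so that the whole copy can be amplified by PCR. The aim stated for the series was to set variants of an improved protocol beside the commercial one. The labels describe 76 libraries in 15 groups, 63 human and 13 mouse. Single HEK293T cells, from a human embryonic kidney line, were taken through Smart-Seq2 (7 cells), 4 variants of it (8, 8, 6 and 6 cells for variants 1 to 4) and SMART-Seq (4 cells). The labels do not say how the variants differ. HEK293T total RNA was diluted to 1 ng (3 libraries), 100 pg (3) and 10 pg (2), and pools of 100, 50 and 10 HEK293T cells were lysed (3 libraries each). Smart-Seq2 was also applied to single cells of DG-75, a human B lymphoma line (7 cells), of C2C12, a mouse myoblast line (6 cells), and of mouse embryonic fibroblasts (MEFs, 7 cells).

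Reads assigned to genes numbered 2.87 to 3.76 M per library (1 M being 1000000 reads) for 1 ng of RNA, 3.58 to 4.10 M for 100 pg and 1.88 to 2.32 M for 10 pg. The range was 3.64 to 5.55 M for 100 cells, 3.48 to 4.35 M for 50 cells and 3.23 to 4.13 M for 10 cells. Single HEK293T cells had 5.29 to 16.6 M with Smart-Seq2, 12.8 to 16.7 M with SMART-Seq, and 7.37 to 14.5, 5.34 to 11.01, 7.63 to 27.9 and 10.3 to 15.5 M with variants 1 to 4. DG-75 cells had 2.24 to 7.88 M, C2C12 cells 3.58 to 9.88 M and MEFs 3.18 to 9.48 M. Tested genes below are given as a log2 fold change of the first group over the second, in parentheses after the symbol, or as the mean ± SD of reads per M of gene reads (CPM) scaled by TMM, over the libraries of each group.

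Libraries from 100 lysed cells and from 1 ng of purified RNA of the same line were compared to ask how far the source of the RNA changes the measured transcriptome, and most genes differed in the main fit. Most transcripts of ribosomal proteins and of the respiratory chain were higher from lysed cells, as were 3 of 4 nuclear long non-coding RNAs. MALAT1 was at 4588 ± 2230.0 CPM in 100 cells and 489 ± 16.5 CPM in RNA (log2 fold change 3.23 ± 0.28 SE, adjusted p = 1.72e-08). DAPK3, a kinase linked to cell death, was at 0.733 ± 0.760 CPM in 100 cells and 97.4 ± 17.5 CPM in RNA (log2 fold change -6.81 ± 0.39 SE, adjusted p = 1.6e-10). JUN, an immediate early transcription factor, was at 14.4 ± 1.63 CPM in cells and 205 ± 31.7 CPM in RNA (adjusted p = 1.3e-10). In edgeR 3406 genes were higher in 100 cells and 3802 lower, of 11487 tested; 1878 and 2679 of these differed by more than 1 on the log2 scale. In 66.6% of the genes the ranges of the groups did not overlap, where chance gives 10%.

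The named genes with the largest differences were higher in cells for SNAR-I (4.32), a small RNA with many near-identical copies whose read assignment is uncertain, MALAT1, AEBP2 (3.22), PAN3 (3.15) and SHISA2 (3.03), the microRNA host MIR17HG (3.01), STRN3 (2.94) and the complex I subunit NDUFB3 (2.89). They were lower in cells for DAPK3, TMEM63B (-6.64), LLGL1 (-6.32) and KLHL11 (-6.09), the anaphase-promoting complex subunit ANAPC2 (-5.92), MYBBP1A (-5.47), CLSTN3 (-5.32) and ANKRD52 (-5.28). For each of these genes the 3 libraries of one group all lay above the 3 of the other. Of 75 ribosomal protein genes 73 were higher and 0 lower (74 and 0 adjusted over the list alone), with RPL38 at 2.31 and RPS2, which has pseudogenes, at 2.36. The list's median was 1.10 (camera adjusted p = 1.22e-20, and adjusted p = 0.412 with an estimated correlation). Of 78 nuclear genes of oxidative phosphorylation 69 were higher, such as NDUFA1 (2.30) and COX6C (2.38), and 2 lower, the complex II subunits SDHC (-2.36) and SDHA (-0.93) (70 and 2 adjusted over the list alone). Their median was 1.42 (camera adjusted p = 2.83e-22, and adjusted p = 0.403 with an estimated correlation). Of 4 nuclear long non-coding RNAs 3 were higher, among them NEAT1 (2.52) (3 and 0 adjusted over the list alone; camera adjusted p = 0.0181, and adjusted p = 0.412 with an estimated correlation). Of 14 host genes of small nucleolar RNAs 11 were higher and 0 lower, the same counts adjusted over the list alone (camera adjusted p = 0.00281, and adjusted p = 0.447 with an estimated correlation). Of 9 immediate early genes 7 were lower, including JUN (-3.84) and ATF3 (-2.48), and 0 higher (0 and 7 adjusted over the list alone; camera adjusted p = 0.0063, and adjusted p = 0.425 with an estimated correlation). Of 16 cholesterol synthesis genes 6 were higher, including the early isoprenoid enzymes IDI1 (1.66) and FDPS (1.09), and 9 lower, including lanosterol synthase LSS (-2.92) and the regulator SREBF2 (-4.19) (6 and 9 adjusted over the list alone; camera adjusted p = 0.0416, and adjusted p = 0.403 with an estimated correlation). Of 5 contractile genes 3 were lower, including filamin A (FLNA, -3.73) and vinculin (VCL, -1.94), and 0 higher (0 and 3 adjusted over the list alone; camera adjusted p = 0.0134, and adjusted p = 0.403 with an estimated correlation).

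The remaining 14 lists tested did not pass camera, and their counts were equal whether adjusted over all genes or adjusted over the list alone. Fry in its directional form asks whether the genes of a list shift in 1 direction. In this form G1/S, kidney and neural, glycolysis, histone, B cell and neuronal genes passed as lower. MHC class II genes and small nucleolar RNAs passed as higher (fry adjusted p from 0.000631 to 0.0376 over these lists), and the others of the 14 did not pass. In its mixed form, which asks for changes in either direction, all 14 lists passed (fry mixed adjusted p from 3.14e-06 to 0.0150). The genes higher and lower numbered 3 and 5 of 17 histone genes, 2 and 0 of 6 small nucleolar RNAs, 4 and 9 of 22 G1/S genes and 10 and 7 of 23 G2/M genes. They numbered 3 and 4 of 12 heat shock genes, 3 and 4 of 13 genes of endoplasmic reticulum stress, 6 and 8 of 17 glycolysis genes and 1 and 9 of 15 kidney and neural markers of HEK293T. Among markers of other cell types they numbered 1 and 2 of 4 B cell genes, 3 and 0 of 3 MHC class II genes, 2 and 4 of 7 MHC class I genes, 2 and 1 of 7 myogenic genes, 4 and 4 of 15 fibroblast and matrix genes and 1 and 1 of 3 neuronal genes. Macrophage, endothelial, epithelial and T cell markers had fewer than 3 tested members here, and the mitochondrially encoded genes in every comparison. With library totals in place of TMM the median of all genes moved by -0.23 and the split became 2501 higher and 4535 lower, and limma on RPKM gave 2521 and 4431. With all 6 input groups in 1 fit 3849 genes were called.

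At the lower input, 10 lysed cells against 100 pg of RNA, the same comparison was made in libraries shared with no other comparison of cells with RNA, and fewer genes were called. Most respiratory chain transcripts were again higher from cells, and 5 of 13 histone genes were lower. NDUFB3 was at 179.5 ± 4.29 CPM in 10 cells and 56.7 ± 7.93 CPM in 100 pg (log2 fold change 1.66 ± 0.17 SE, adjusted p = 3.22e-05). CASC5, a kinetochore scaffold, was at 74.1 ± 13.8 CPM in 10 cells and 871 ± 104 CPM in 100 pg (log2 fold change -3.55 ± 0.15 SE, adjusted p = 9.41e-08). In edgeR 911 genes were higher in 10 cells and 1341 lower, of 11671 tested, and 296 and 862 of these differed by more than 1 on the log2 scale. In 37.7% of the genes the ranges did not overlap, against 10% by chance. The largest named differences were higher in cells for NPTN (3.16), SHISA2 (2.98), GTPBP2 (2.69), SLC18A2 (2.68), DHRS3 (2.54), TMEM161B (2.36), TOB1 (2.34) and LINC00116 (2.30). They were lower for DLST (-4.33), PLCG1 (-4.00), APP (-3.97) and PTK7 (-3.76), the membrane scission protein CHMP4B (-3.73), the linker histone HIST1H1E (-3.59), CASC5 (-3.55) and lamin B1 (LMNB1, -3.49). Of 78 oxidative phosphorylation genes 48 were higher, including NDUFB3 (1.66) and COX6C (1.27), and 1 lower, SDHC (-2.02) (53 and 1 adjusted over the list alone; median 0.55; camera adjusted p = 2.67e-21, and adjusted p = 0.278 with an estimated correlation). Of 75 ribosomal protein genes 19 were higher, including RPL27 (1.22) and RPL38 (1.33), and 1 lower, RPS4X (-0.40) (23 and 2 adjusted over the list alone; median 0.17; camera adjusted p = 0.000234, and adjusted p = 0.817 with an estimated correlation); after the trend with transcript length and GC content was removed, 12 were higher and 18 lower and the median was -0.14. Of 13 histone genes 5 were lower, including HIST1H1E and HIST1H2AH (-2.64), and 0 higher (0 and 6 adjusted over the list alone; median -1.22; camera adjusted p = 0.00996, and adjusted p = 0.278 with an estimated correlation). Histone genes have near-identical copies, so the assignment of their reads is uncertain. Of 10 immediate early genes 3 were lower, including JUN (-3.28) and DUSP1 (-0.87), and 0 higher (0 and 3 adjusted over the list alone; camera adjusted p = 0.0432, and adjusted p = 0.386 with an estimated correlation). Of 6 contractile genes 2 were lower, FLNA (-2.07) and VCL (-1.56), and 0 higher (0 and 3 adjusted over the list alone; camera adjusted p = 0.00266, and adjusted p = 0.278 with an estimated correlation). The other 17 lists tested did not pass, the lowest camera adjusted p being 0.123 for the small nucleolar RNA hosts. Of 3 epithelial markers 0 were higher and 0 lower. By fry in its directional form the ribosomal protein genes did not pass (adjusted p = 0.0729). Small nucleolar RNA hosts (0.0300), heat shock genes (0.0300) and nuclear long non-coding RNAs (0.0442) did. Without HEK_10cells replicate 1 the count fell to 1252 genes, without HEK_10cells replicate 2 to 1400, and with all 6 input groups in 1 fit to 1117. Limma on RPKM gave 1235 higher and 1163 lower.

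Over the 11294 genes tested at both inputs, the log2 fold changes of cells over RNA had a Pearson correlation across genes of 0.69, genes not being independent replicates. Genes higher in cells at both inputs numbered 780, where independent calls would give 269, and genes lower at both numbered 1205, where they would give 444; 18 were called in opposite directions. Among the 2003 genes called at both inputs in either direction, the median absolute log2 fold change was 1.60 at the higher input and 1.05 at the lower. The difference between inputs was itself tested by an interaction in edgeR, where 882 genes had a higher ratio of cells to RNA at the higher input and 1306 a lower one, of 12192 tested. Among genes named above, the log2 interaction was 2.61 for RPS2, 1.91 for MALAT1, 1.11 for COX6C, 0.99 for RPL38, -3.44 for DAPK3 and -1.65 for FLNA, and all of these passed. SHISA2 (0.05, adjusted p = 0.96) and JUN (-0.55, adjusted p = 0.293) did not pass. Without HEK_100cells replicate 1 the interaction was called in 1385 genes. Restricted to the libraries with shared replicate numbers it was called in 735, or in 964 with the number as a block.

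The difference between cells and RNA followed transcript length and GC content, for which 98.99% of the symbols with a mean of at least 1 CPM had a value. The rank correlation across genes of the log2 fold change of 100 cells over 1 ng with length was -0.34 and with GC content -0.41, and both terms together took 40.7% of its variance. Median log2 fold changes were 0.78, 0.13, -0.23, -0.42 and -0.35 from the shortest to the longest of 5 equal groups of transcripts, and 0.45, 0.25, 0.03, -0.40 and -1.04 from the lowest to the highest GC content. For 10 cells over 100 pg the rank correlations were -0.36 and -0.23. The trend was not particular to cells against RNA. Between pools of cells the rank correlations were -0.33 and -0.28 for 100 over 10 cells and -0.35 and -0.15 for 100 over 50 cells. The libraries of 100 cells are the same in these comparisons and in that with 1 ng. With this trend removed, 6353 genes were called for 100 cells against 1 ng, 3370 higher and 2983 lower; 2072 were higher and 2221 lower both before and after, and 355 changed direction. Ribosomal protein genes then numbered 39 higher and 6 lower, oxidative phosphorylation genes 59 and 4, nuclear long non-coding RNAs 4 and 0, small nucleolar RNA hosts 6 and 2, immediate early genes 0 and 5, cholesterol genes 4 and 8 and contractile genes 1 and 4. Their medians were then 0.27, 0.64, 2.10, 0.23, -0.50, -0.38 and -0.92, where they had been 1.10, 1.42, 1.73, 0.97, -1.32, -1.11 and -1.94. Histone genes numbered 1 higher and 9 lower, with a median of -0.86 where it had been -0.17. At the lower input 1374 genes were called, 581 higher and 793 lower, of which 399 and 631 were called in the same direction before, and 1 changed direction. Oxidative phosphorylation genes then numbered 27 higher and 2 lower, histone genes 0 and 7, immediate early genes 0 and 3 and contractile genes 0 and 2 (medians of 0.29, -1.64, -0.03 and -0.49).

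**Figure D1:**
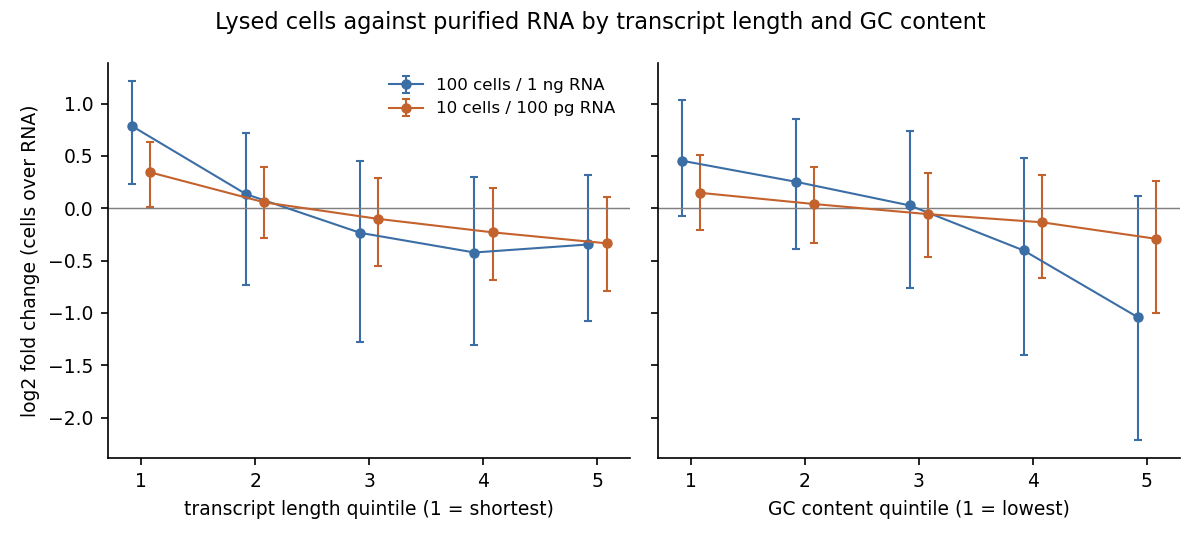
Median log2 fold change of lysed cells over purified RNA (vertical axis) by quintile of transcript length and of GC content (horizontal axes), with bars for the interquartile range, for 100 cells over 1 ng and for 10 cells over 100 pg. Short transcripts and transcripts low in GC lay above 0, and those highest in GC had a median of -1.04 at the higher input.

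The effect of the number of lysed cells was asked by comparing pools of 100 and 10 cells. Most ribosomal protein and respiratory chain transcripts were higher in pools of 100 cells, and several genes of cholesterol synthesis were lower. RPS2 was at 368 ± 26.8 CPM in 100 cells and 52.9 ± 3.77 CPM in 10 cells (log2 fold change 2.80 ± 0.16 SE, adjusted p = 7.43e-07). POLR2A, a catalytic subunit of RNA polymerase II, was at 18.8 ± 10.7 and 177 ± 34.0 CPM (log2 fold change -3.21 ± 0.31 SE, adjusted p = 2.62e-05). In edgeR 1568 genes were higher in 100 cells and 1999 lower, of 11514 tested; 482 and 1226 differed by more than 1 on the log2 scale, and the ranges did not overlap in 43.7% of the genes, against 10% by chance. The 100 most abundant genes took 20.2 ± 0.324% of the reads in 100 cells, 16.5 ± 1.41% in 50 cells and 14.8 ± 0.611% in 10 cells. The largest named differences were higher in 100 cells for SNAR-I (5.14), MESP1 (2.93) and FAM58A (2.84), RPS2, MRPL23 (2.56), GAL (2.54), DNTTIP1 (2.47) and C20orf24 (2.38). They were lower for KLHL11 (-3.94), CNOT3 (-3.92), ANKRD52 (-3.57), GANAB (-3.27) and ARHGDIA (-3.23), POLR2A, PPDPF (-3.20) and AP2A1 (-3.20). Of 75 ribosomal protein genes 71 were higher, including RPS24 (1.38), and 0 lower (74 and 0 adjusted over the list alone; median 1.06; camera adjusted p = 7.08e-47, and adjusted p = 0.251 with an estimated correlation). Of 78 oxidative phosphorylation genes 66 were higher, including COX7C (1.58) and ATP5O (1.32), and 1 lower, SDHA (-0.91) (66 and 1 adjusted over the list alone; median 0.94; camera adjusted p = 9.08e-31, and adjusted p = 0.251 with an estimated correlation). Of 13 histone genes 4 were higher, including HIST1H4C (1.53) and HIST1H1C (1.63), and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00705, and adjusted p = 0.442 with an estimated correlation). Of 15 small nucleolar RNA hosts 7 were higher, including SNHG8 (0.91) and SNHG5 (0.83), and 0 lower (7 and 0 adjusted over the list alone; median 0.54; camera adjusted p = 0.00785, and adjusted p = 0.468 with an estimated correlation). With the length and GC trend removed, 1 host gene was higher and 1 lower and the median was -0.05, and the genes higher and lower numbered 55 and 0 for ribosomal proteins, 48 and 3 for oxidative phosphorylation, 4 and 0 for histones and 2 and 7 for cholesterol synthesis (medians of 0.53, 0.38, 0.18 and -0.32). Of 16 cholesterol genes 2 were higher, FDPS (0.61) and IDI1 (0.82), and 10 lower, including the late enzyme DHCR7 (-1.16) (2 and 10 adjusted over the list alone; median -0.67; camera adjusted p = 0.0156, and adjusted p = 0.251 with an estimated correlation). The other 16 lists tested did not pass, the lowest camera adjusted p being 0.118 for the immediate early genes. Without HEK_100cells replicate 1 the count was 2174, and with all 6 groups in 1 fit 1611. Library totals in place of TMM moved the median by -0.26 and gave 851 higher and 3119 lower, and limma on RPKM gave 890 and 2920.

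The smaller step, from 100 to 50 cells, gave differences that did not pass the test gene by gene. Ribosomal protein genes had a median log2 fold change of 0.54: RPS14 was at 3980.0 ± 185 CPM in 100 cells and 2593 ± 733 CPM in 50 cells (0.62, adjusted p = 0.448), and RPL8 had a log2 fold change of 0.56 (adjusted p = 0.478). UQCRQ and ATP5B of the respiratory chain had 0.65 and 0.34 (adjusted p = 0.448 and 0.563). In edgeR 0 of 11354 genes passed, 1005 had an unadjusted p under 0.05, and DESeq2 called 63. The ranges did not overlap in 15.3% of the genes, against 10% by chance. As a list, the 75 ribosomal protein genes ranked high (0 higher and 0 lower over all genes, 33 and 0 adjusted over the list alone; camera adjusted p = 3.97e-40, and adjusted p = 0.487 with an estimated correlation). So did the 78 oxidative phosphorylation genes (0 and 0, 0 and 0 adjusted over the list alone; median 0.47; camera adjusted p = 2.41e-28, and adjusted p = 0.487 with an estimated correlation). The 14 small nucleolar RNA hosts also passed (0 and 0, 0 and 0 adjusted over the list alone; median 0.24; camera adjusted p = 0.00701, and adjusted p = 0.695 with an estimated correlation), and the other 18 lists did not, the lowest camera adjusted p being 0.0549 for the small nucleolar RNAs. With the length and GC trend removed the medians of these 3 lists were 0.28, 0.23 and -0.02, with 6 ribosomal protein genes higher. Library totals in place of TMM moved the median of all genes by -0.20. Libraries with the same replicate number had correlations of 0.31, 0.73 and 0.82 between deviations from the group means for numbers 1 to 3, and the highest with another number was 0.65 for number 1. With the number as a block 951 genes were higher and 631 lower, including 65 of the 75 ribosomal protein genes and 57 of the 78 oxidative phosphorylation genes, with 0 and 1 lower. Without HEK_100cells replicate 3 and without a block 43 genes passed.

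Dilution of purified RNA was examined to see how far a smaller input alone changes the profile. From 1 ng to 100 pg almost nothing passed. CASC5 was at 92.4 ± 9.33 CPM in 1 ng and 867 ± 104 CPM in 100 pg (log2 fold change -3.23 ± 0.13 SE, adjusted p = 2.7e-07). CHMP4B was at 3.83 ± 0.314 and 40.3 ± 5.79 CPM (-3.38 ± 0.32 SE, adjusted p = 0.00166). In edgeR 0 genes were higher in 1 ng and 3 lower, of 11469 tested; 888 had an unadjusted p under 0.05 and DESeq2 called 25. The ranges did not overlap in 14.99% of the genes, against 10% by chance. Ribosomal protein genes had a median of 0.12, RPL8 at 0.31 and RPS4X at -0.05; 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00207, and adjusted p = 0.851 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.12, ATP5B at 0.13 and ATP5A1 at 0.10; 0 and 0 passed over all genes, 0 and 0 adjusted over the list alone (camera adjusted p = 0.000538, and adjusted p = 0.773 with an estimated correlation). With the length and GC trend removed the medians were 0.03 and 0.07. The other 19 lists did not pass, the lowest camera adjusted p being 0.179 for the G2/M genes. Without HEK_RNA_1ng replicate 2 the count was 1. Without CASC5, PDCD4 and CHMP4B, a set chosen after their values were seen, it was 0.

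At 10 pg, of the order of the RNA of a cell, many transcripts seen at 1 ng had no reads. Over both 10 pg libraries PIK3C2A, a lipid kinase, had 0 reads. Its level in 1 ng was 124.2 times that of 3 reads over the 10 pg group. The same held for TIMM10B, of mitochondrial protein import (121.8 times), ODF2 (105), UTP15 (104), MPP1 (101.02), MGA (97.6), RSPRY1 (93.4) and C17orf62 (91.0). These values cover counting error only, so they do not bound the ratio of transcripts. CASC5 was at 93.9 ± 10.3 CPM in 1 ng and 9520.2 ± 1804 CPM in 10 pg (log2 fold change -6.66 ± 0.20 SE, adjusted p = 0.00826). CHMP4B had -6.57, and lower in 1 ng were also ADCYAP1R1 (-3.95), SLC35D3 (-3.87), ZNF585B (-3.81), RASSF8 (-3.72), TMEM65 (-3.68) and LBX2-AS1 (-3.65). In edgeR 1873 genes were higher in 1 ng and 171 lower, of 11087 tested. With the length and GC trend removed 1768 were higher and 421 lower. Of 4 nuclear long non-coding RNAs 2 were lower in 1 ng, TUG1 (-1.47) and NEAT1 (-2.99), and 0 higher (0 and 2 adjusted over the list alone; camera adjusted p = 0.0478, and adjusted p = 0.497 with an estimated correlation). Of 3 small nucleolar RNAs 1 was lower, SNORA70 (-2.28), and 0 higher (0 and 2 adjusted over the list alone; camera adjusted p = 0.00961, and adjusted p = 0.497 with an estimated correlation). The 23 G2/M genes passed camera in the downward direction, with 1 gene higher and 1 lower (1 and 1 adjusted over the list alone), a median of -0.06 and a mean of 0.05 (camera adjusted p = 0.0478, and adjusted p = 0.497 with an estimated correlation). With the length and GC trend removed, the genes higher and lower numbered 1 and 5 for G2/M (median -0.42), 0 and 3 for nuclear long non-coding RNAs (median -1.33) and 0 and 1 for small nucleolar RNAs (median -2.57). The other 18 lists did not pass, the lowest camera adjusted p being 0.258 for the fibroblast and matrix genes. Without any 1 of the 3 HEK_RNA_1ng replicates, 1, 2 or 3, the count was 0, without HEK_RNA_10pg replicate 1 it was 8516 and without HEK_RNA_10pg replicate 2 it was 8043. The stricter filter gave 959 genes, all 6 groups in 1 fit 4298, and simulated 4-fold changes were recovered in 0% of genes. That simulation gave both groups the same dispersion per gene, so it did not mimic the larger spread of the 10 pg libraries.

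CASC5 and CHMP4B, and PDCD4, an inhibitor of translation that was chosen after its values were seen, were higher, on average over the cells, in single HEK293T and DG-75 cells taken through unmodified Smart-Seq2 than in the diluted RNA or the pools. PDCD4 was at 761 CPM on average in variant 3 cells and CHMP4B at 319 CPM in variant 4 cells, below the 1894 and 380 CPM of 10 pg. In variant 3 cells CASC5 ranged from 25.1 to 171623 CPM, 4 of the 6 cells having at most 153.2 CPM. CASC5 was at 92.2 ± 8.25 CPM in 1 ng, 862 ± 102.4 in 100 pg and 9671 ± 1867 in 10 pg, without TMM factors. It was at 48.8 ± 16.7 CPM in 100 cells, 50.7 ± 14.1 in 50 cells and 74.4 ± 14.4 in 10 cells. Single HEK293T cells had 50677 ± 39114 CPM with Smart-Seq2 and 119 ± 94.1 CPM with SMART-Seq, and DG-75 cells had 44784 ± 13475 CPM. PDCD4 was at 9257 ± 7299 CPM in single Smart-Seq2 cells and 164 ± 34.6 CPM in 100 cells. The 3 genes together took 6.15% of the reads of a Smart-Seq2 HEK293T cell on average and up to 15.1%.

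**Figure D2:**
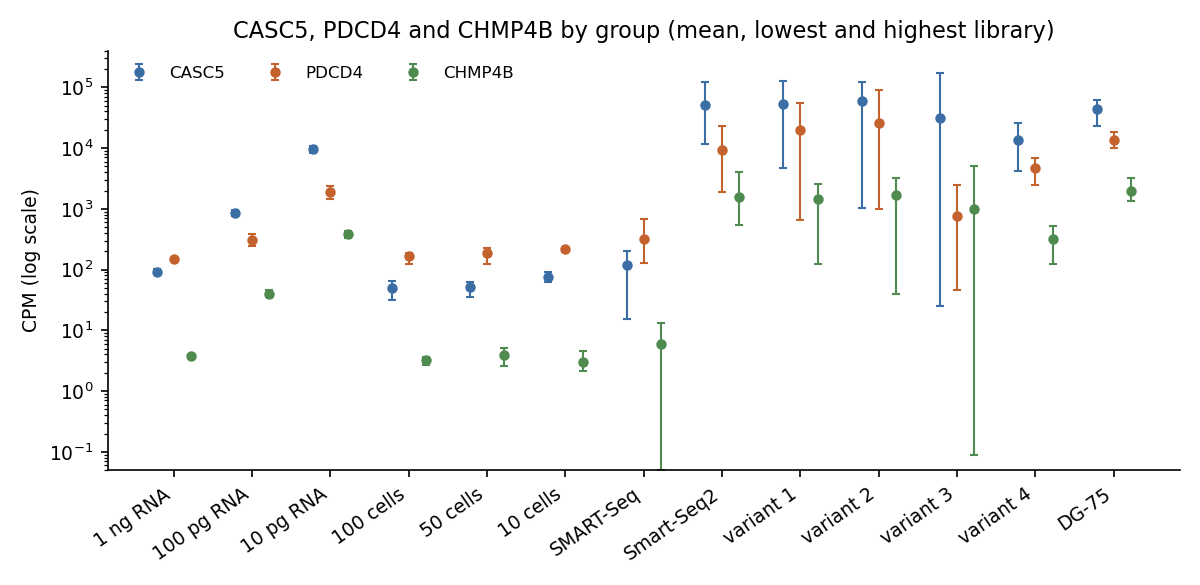
Mean CPM of CASC5, PDCD4 and CHMP4B (log axis) in 13 human groups, with bars from the lowest to the highest library; values under 0.05 CPM are drawn at 0.05. CASC5 rose from 92.2 CPM in 1 ng of RNA to 9671 CPM in 10 pg, and lay between 48.8 and 74.4 CPM in pools of 10 to 100 cells.

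The number of genes seen per library was compared at 1.8 M gene reads to ask how input limits sensitivity. Libraries from 1 ng had 14262 ± 55.5 genes with a read, from 100 pg 13079 ± 134 and from 10 pg 8624 ± 299.8. Pools of 100, 50 and 10 cells had 14121 ± 73.2, 14298 ± 58.03 and 14013 ± 156. Libraries from 1 ng thus lay above those from 100 pg, without overlap (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow, adjusted 0.188 over 15 pairs of groups). Counting genes with an RPKM of at least 1, they had 11595 ± 107.6 and 11449 ± 75.4, and the ranges overlapped. At 1.8 M gene reads pools of 10 cells lay above 100 pg by 934 genes (exact p = 0.1). With an RPKM of at least 1 they lay closer, at 11655 ± 79.4 and 11449 ± 75.4 genes. Comparisons with 10 pg could not go below an exact p of 0.2, the value found for 1 ng (adjusted 0.231). The difference between 100 and 10 cells was within the spread of the libraries (exact p = 0.4), and it turned to -545 for genes with at least 5 reads. The difference of -140 between 100 cells and 1 ng (exact p = 0.1) became 351 at deposited depth. Over the 9049 genes at a mean of at least 10 CPM, the median SD of log2(CPM + 1) between libraries was 0.178 for 1 ng, 0.290 for 100 pg and 0.814 for 10 pg. It was 0.256 for 100 cells, 0.238 for 50 cells, 0.223 for 10 cells and 1.22 for single Smart-Seq2 cells. Without HEK_100cells replicate 3 the difference between 10 and 100 cells turned from negative to 0.132, and without HEK_SS2 cell 2 single cells exceeded pools of 10 cells by 0.620.

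**Figure D3:**
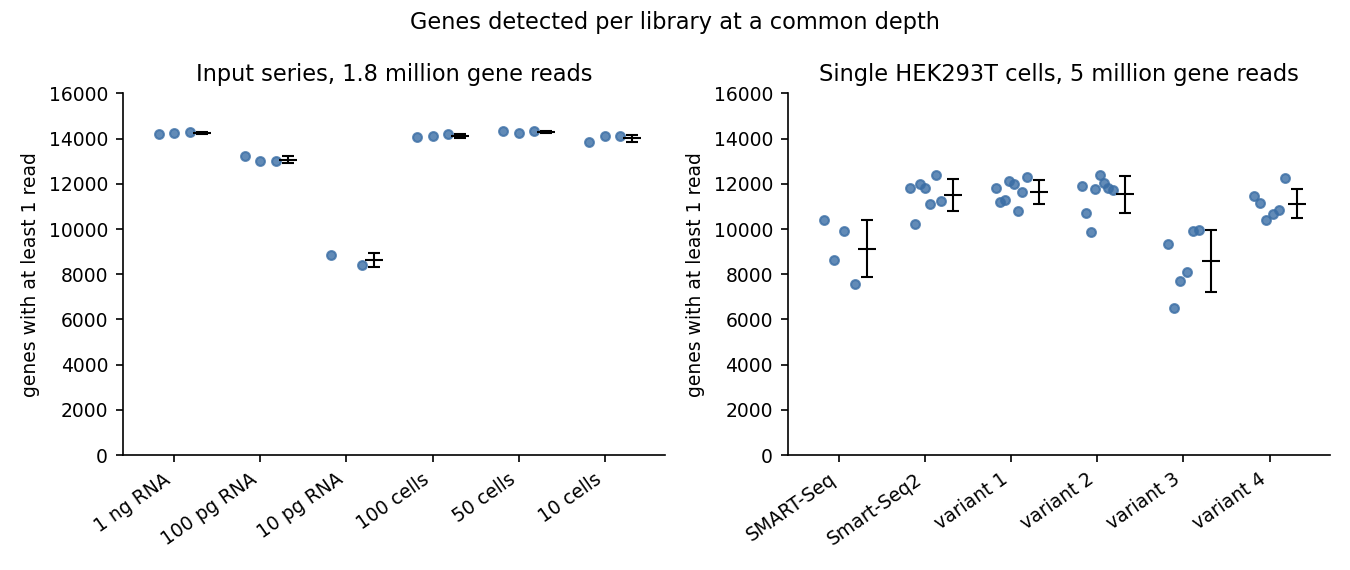
Genes with at least 1 read per library, for the input series at 1.8 M gene reads (left) and for single HEK293T cells at 5 M (right); points are libraries, with mean and SD. The 10 pg libraries lay between 8412 and 8836 genes, below all other libraries of the input series.

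Single HEK293T cells processed with SMART-Seq and with Smart-Seq2 were compared to ask what the improved protocol changes; each group counts as 1 sample, so no test was made and ratios describe these cells only. At 5 M gene reads SMART-Seq cells had 9130.5 ± 1271 genes with a read and Smart-Seq2 cells 11507 ± 714, and the mean correlation between cells was 0.665 and 0.712 (0.765 without HEK_SS2 cell 2). Genes seen in every cell numbered 5264 and 7229. Summed over cells, CASC5 was at 117 CPM with SMART-Seq and 47049 CPM with Smart-Seq2 (95% counting intervals 114.2 to 119.8 and 47001 to 47097), and MALAT1 at 12789 and 1467 CPM. Thymidylate synthase (TYMS, log2 ratio -5.08) and the sterol regulators INSIG1 (-5.57) and SREBF2 (-4.33) were lower with SMART-Seq. INSIG1 was at 20.8 CPM in SMART-Seq cells and 1039 CPM in Smart-Seq2 cells.

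The largest log2 ratios of SMART-Seq over Smart-Seq2 were those of GPR22 (6.01; seen in 3 of 4 and 1 of 7 cells), SLC24A2 (5.98), SHISA2 (5.63) and GPR171 (5.62), the death receptor FAS (5.37), NHSL1 (5.01), SERINC5 (4.86) and RDH10 (4.86). The lowest were those of CASC5 (-8.64), CHMP4B (-7.73) and KLHL11 (-7.49), the replication helicase subunit MCM5 (-7.42), MRPL12 (-7.37), NHLRC2 (-7.10), DDIT4 (-6.84) and RRP1 (-6.62). Among lists, set against the central 95% of 10000 random lists of like expression, 37 of 79 oxidative phosphorylation genes were at least 2 times higher and 6 at least 2 times lower (median 0.93; random lists -0.05 to 0.63). COX6A1 (3.12) and SDHD (3.04) were higher, ATP5D (-4.32) and COX5A (-3.08) lower. Of the small nucleolar RNAs, 26 of 55 genes were at least 2 times higher and 8 at least 2 times lower (median 0.97; random lists -1.73 to -0.41), SNORD80 at 2.38 and SNORD47 at 2.10. Of the G1/S genes, 0 of 22 genes were at least 2 times higher and 15 at least 2 times lower (median -1.69; random lists -0.83 to 0.60), and of the cholesterol genes 1 of 16 genes were at least 2 times higher and 10 at least 2 times lower (median -1.55; random lists -0.87 to 0.77). Histone, B cell and MHC class II genes also lay above the random range, with medians of 0.43, 2.63 and 1.70, but cell by cell, each cell set beside the summed Smart-Seq2 cells, the medians ran from -1.79 to 0.57, -0.24 to 1.05 and -1.63 to 2.41. Those of the small nucleolar RNAs ran from -0.25 to 1.09, and those of the oxidative phosphorylation, G1/S and cholesterol genes had 1 sign. The ribosomal protein genes lay within it (0.63; random lists -0.05 to 0.64), with RPL27 at 2.01 and RPL23A at 1.95, as did the other 14 lists. About 1 in 20 lists of genes that vary independently lies outside by chance, and lists whose genes vary together do so more often. The ratio fell with GC content, from a median of 0.23 in the fifth of transcripts lowest in GC to -1.82 in the fifth highest (rank correlation across genes -0.37). The random lists were not matched on GC content, so lists outside their range cannot be told apart from this trend.

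Each variant was set beside Smart-Seq2 in the same way, to describe which transcripts its cells gained or lost. Variant 1 cells had 11649 ± 527 genes at 5 M reads and a correlation between cells of 0.761. Smart-Seq2 had 0.712, or 0.765 without its cell 2, and variant 1 had 0.768 without its own lowest cell, cell 6. The order of both groups thus turned on the cells left out. The immediate early gene EGR1 (3.73) and CTGF (3.51) were higher, and heme oxygenase HMOX1 (-4.01) and NDRG1 (-2.45) and the amino acid transporter SLC7A5 (-2.41) were lower. Immediate early genes as a list lay within the random range (median 0.03; random lists -0.45 to 0.44; 2 and 1 of 13 at least 2 times higher and lower). The remaining largest ratios were SHISA2 (2.82), TIMP1 (2.19), ZDHHC17 (2.14), FZD7 (2.02), HIST1H4C (2.00) and TOB1 (1.89) on the high side and CALCB (-4.57), ICK (-2.37), HES4 (-2.36), BTG1 (-2.27) and RHOB (-2.25) on the low side. Cholesterol genes had a median of -0.51 (random lists -0.22 to 0.20; 0 of 16 at least 2 times higher and 4 lower), with MVK (-1.39) and LSS (-1.14). Genes of endoplasmic reticulum stress had -0.43 (random lists -0.26 to 0.26; 1 and 3 of 14), with XBP1 (-1.95) and TRIB3 (-1.49). Histone genes had 0.60 (random lists -0.40 to 0.43; 10 and 3 of 23), HIST2H2AC at 2.57. Ribosomal protein genes lay below the random range (-0.19) and oxidative phosphorylation genes above it (0.15), both by less than 2 times, and the other 17 lists lay within. Cell by cell the medians ran from -1.21 to 2.46 for histones, -0.72 to 0.14 for ribosomal proteins and -0.46 to 0.66 for oxidative phosphorylation.

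Variant 2 cells had 11533 ± 828 genes and a correlation of 0.731; their difference from Smart-Seq2, 26.1 genes, was within the spread of the cells and became -164 for genes with at least 5 reads. Summed over cells, histone transcripts were higher and transcripts of sterol regulation and synthesis lower: HIST1H1D had a log2 ratio of 4.87 and INSIG1 -3.30. Histone genes had a median of 1.41 (random lists -0.42 to 0.37), with 14 of 26 at least 2 times higher and 3 lower, including HIST1H2AC (3.77), HIST1H4C (2.73), HIST1H1C (2.51) and HIST1H1E (2.20), but cell by cell the median ran from -1.55 to 2.20. It ran from -1.54 to -0.78 for cholesterol, -1.77 to 0.52 for endoplasmic reticulum stress, -1.72 to 1.35 for nuclear long non-coding RNAs, -1.67 to 1.35 for immediate early and -0.44 to 0.30 for ribosomal protein genes. Other high ratios were ANKRD30BL (2.71), SYTL5 (2.49), SHISA2 (2.38), ANKRD1 (2.36) and KLF10 (2.29). Low ratios were those of the chemokine receptor CXCR4 (-4.31), CALCB (-3.45), SAC3D1 (-3.16), LRRC8B (-3.15), VAC14 (-3.05) and HES4 (-2.98). Cholesterol genes had a median of -1.01 (random lists -0.27 to 0.20; 0 and 8 of 16), and genes of endoplasmic reticulum stress -0.68 (random lists -0.32 to 0.25), with ASNS (-1.54) and XBP1 (-1.52). G2/M genes had -0.47 (random lists -0.20 to 0.13; 0 and 3 of 23), with the centromeric histone CENPA (-2.73) and KIF20A (-1.12). Medians also lay outside the random range for ribosomal protein genes (-0.22), nuclear long non-coding RNAs (0.79), immediate early genes (0.64), fibroblast and matrix genes (-0.75) and 3 endothelial genes (1.83), and within it for the other 14 lists.

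Variant 3 cells had fewer genes, 8585 ± 1373, with 4316 seen in every cell and a correlation of 0.713. Transcripts rich in GC were much lower: the median log2 ratio to Smart-Seq2 was 0.66 in the fifth lowest in GC and -3.51 in the fifth highest (rank correlation across genes -0.57). CHAC1, a glutathione-degrading enzyme induced by stress, had 0 reads and was at least 1426-fold lower over the group. The lowest log2 ratios among named genes were those of DDIT4 (-7.94), MRPL12 (-7.92), COPE (-7.76), WDR34 (-7.66), BSG (-7.66), PLD3 (-7.43), MAF1 (-7.29) and SMARCB1 (-7.12), and among the highest were those of ANKRD44 (5.65), KIAA2018 (5.27), SHISA2 (4.76), KRT222 (4.49), ZNF624 (4.30), PRKCB (4.28) and KLRG1 (4.15). G1/S genes had a median of -1.40 (random lists -0.79 to 0.86; 3 and 12 of 22 at least 2 times higher and lower), with CDT1 (-6.04) and SLBP (-4.52). Genes of endoplasmic reticulum stress had -2.15 (random lists -1.72 to 0.79; 0 and 11 of 14), with TRIB3 (-3.96). Cholesterol genes had -1.68 (random lists -0.97 to 0.98; 1 and 10 of 16), with DHCR7 (-5.76) and SREBF2 (-5.12), and MHC class I genes -2.94 (random lists -2.75 to 0.77; 0 and 7 of 8), with HLA-B (-4.62) and HLA-C (-3.58). Ribosomal protein genes lay below the random range (-0.14), with RPL27 at 1.31 and RPL13 at -4.79, small nucleolar RNAs above it (0.17), and the other 16 lists within it. Cell by cell the medians of these 2 lists ran from -0.44 to 0.10 and -1.29 to -0.10, and that of G1/S genes from -3.97 to 0.24. The random lists were not matched on GC content, so lists outside their range cannot be told apart from the GC trend.

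Variant 4 cells had 11132 ± 657 genes and a correlation of 0.724. Summed over cells, transcripts of G1/S genes were higher and of G2/M genes lower than in Smart-Seq2 cells: cyclin E1 (CCNE1) had a log2 ratio of 1.67, CDC45 1.28, CENPE -1.75 and CDC20 -1.59. The G1/S median was 0.65 (random lists -0.15 to 0.29; 6 and 0 of 22 at least 2 times higher and lower) and the G2/M median -0.71 (random lists -0.14 to 0.29; 0 and 7 of 23). Histone genes had 0.53 (random lists -0.41 to 0.52; 9 and 5 of 26), with HIST1H1D (4.70), HIST1H4C (3.33), HIST1H1C (3.14) and HIST1H1E (2.50). Ribosomal protein genes had 0.58 (random lists -0.03 to 0.21), with RPS27 (1.27) and RPL30 (1.01), and oxidative phosphorylation genes 0.37 (random lists -0.04 to 0.20). Glycolysis genes (0.39) and 5 epithelial genes (1.40) lay above the random range, and the other 15 lists within it. Cell by cell the medians ran from -0.35 to 0.90 for G1/S, -1.40 to -0.18 for G2/M, -0.98 to 1.09 for histone, -0.05 to 0.68 for glycolysis and -1.84 to 1.91 for epithelial genes. Other high ratios were ANXA1 (2.54), GYPC (2.40), CCND1 (2.37), H1F0 (2.26) and SELM (2.01), and low ones MIR663A (-5.57), INCENP (-5.41), KLHL11 (-5.34), ZNF460 (-4.96), PRPF19 (-4.27), MAPK8 (-4.04), CALCB (-3.82) and RBM33 (-3.57). The median log2 ratio rose from -0.09 in the fifth lowest in GC to 0.22 in the fifth highest (rank correlation 0.18), and in variants 1 and 2 all quintiles lay between -0.12 and 0.02.

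**Figure D4:**
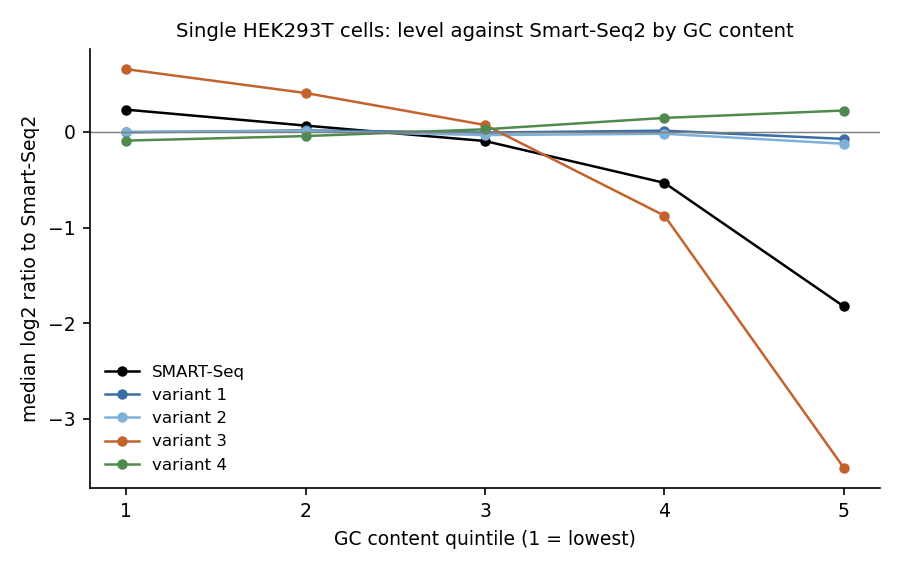
Median log2 ratio of summed CPM to Smart-Seq2 (vertical axis) by quintile of transcript GC content (horizontal axis) for SMART-Seq and variants 1 to 4 in single HEK293T cells. SMART-Seq and variant 3 fell to -1.82 and -3.51 in the fifth highest in GC, and variants 1, 2 and 4 stayed near 0.

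DG-75 and HEK293T cells, both taken through Smart-Seq2, were compared to describe cell identity under 1 protocol; the ratios were not tested. B cell and antigen presentation transcripts separated them: CD74, the invariant chain, was at 2476 CPM over the DG-75 cells with 0 reads in HEK293T (at least 64471-fold), and MS4A1, a B cell surface protein, at 461 CPM with 0 reads (at least 12009.5-fold). HEK293T cells had 644 CPM of IRS4, an insulin receptor substrate, with 0 reads in DG-75 (at least 7874-fold), and 322 CPM of the transcription factor HAND1 (at least 3939.7-fold). At 2 M gene reads DG-75 cells had 9287 ± 488 genes and HEK293T cells 11037 ± 789. LAPTM5 (1271 CPM, at least 33089-fold), IGLL5 (at least 24701-fold) and the immunoglobulin J chain (IGJ, at least 21806-fold) had 0 reads in HEK293T. High log2 ratios, with 1 CPM added to both groups, were also those of the antigen receptor chain CD79A (9.33), ARHGDIB (8.90) and IFI16 (8.67), and low ones those of NGFRAP1 (-9.15), PLS3 (-9.13), TSPAN6 (-8.67), PFN2 (-8.65), SNAR-E (-8.25) and MID1 (-8.23). All 29 of 29 B cell genes and 9 of 9 MHC class II genes were at least 2 times higher (medians 6.04 and 4.28; random lists -0.68 to 0.64 and -1.41 to 1.21), HLA-DRA at 654 against 2.09 CPM. Of MHC class I genes 6 of 9 genes were at least 2 times higher and 0 at least 2 times lower (median 1.38; random lists -1.40 to 1.06), B2M at 5609 against 512 CPM. Of kidney and neural markers 1 of 18 genes were at least 2 times higher and 16 at least 2 times lower (median -3.80; random lists -1.29 to 0.80), with CDH2 (-6.66). Cholesterol genes had a median of -1.83 (random lists -0.71 to 0.75; 0 and 11 of 16), with INSIG1 (-3.71), and heat shock genes -1.66 (random lists -0.82 to 0.73; 0 and 8 of 12), with HSPA1A (-6.97) and HSPH1 (-4.50). Genes of endoplasmic reticulum stress had 1.57 (random lists -0.73 to 0.67; 8 and 1 of 14), with ATF5 (4.62) and TRIB3 (4.04), histone genes 1.95 (31 and 2 of 40), with HIST1H2AM (3.37), and small nucleolar RNA hosts 1.25 (8 and 1 of 15), with GAS5 (3.08) and SNHG6 (2.90). Of 6 macrophage genes measured 5 were at least 2 times higher in DG-75 and 0 lower, lysozyme (LYZ) at 63.6 CPM against 0 reads (at least 1657-fold). Only 3 genes of the T cell list were measured, and all 3 were at least 2 times higher, summing to 231 CPM in DG-75 and 0 in HEK293T. Most of that sum was the kinase LCK, at 211 CPM against 0 reads (at least 5484-fold). Ribosomal protein genes lay above the random range (0.54), and the other 13 lists within it. Cell by cell the medians ran from -0.63 to 0.89 for ribosomal protein, -0.24 to 1.95 for histone, -0.04 to 3.61 for macrophage and 0 to 5.89 for T cell genes.

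C2C12 myoblasts and MEFs were compared in the same way, without a test. C2C12 cells had muscle transcripts: desmin (Des) was at 1169 CPM against 2.97 in MEFs, and Chrna1, a subunit of the muscle acetylcholine receptor, had a log2 ratio of 7.74. MEFs had macrophage transcripts: lysozyme Lyz2 was at 10407 CPM against 7.71 in C2C12 cells, and the receptor Csf1r had a log2 ratio of -9.53. All 12 macrophage genes measured had reads in each of the 7 MEFs, and their summed level was 5336 to 34976 CPM per MEF (mean 20524 ± 10706) and 8.40 to 52.6 CPM per C2C12 cell (34.4 ± 15.7). The summed fibroblast and matrix genes were at 5286 to 37434 CPM per MEF and 9745 to 38706 CPM per C2C12 cell, and the myogenic genes at 58.2 to 455 and 914 to 5263 CPM. At 3 M gene reads C2C12 cells had 10398 ± 456 genes and MEFs 10039 ± 1147. The highest ratios were those of Des (8.20), Peg3 (8.07), Eno3 (8.06), Itga7 (7.92) and Ankrd1 (7.84), Chrna1, Nefl (7.44) and Cacng1 (7.35), and the lowest those of Lyz2 (-10.22), Fcer1g (-9.82) and Laptm5 (-9.62), Csf1r, Ctss (-9.52), Rgs1 (-9.51), Tyrobp (-9.40) and Mpeg1 (-9.33). Of myogenic genes 20 of 23 genes were at least 2 times higher and 1 at least 2 times lower (median 4.26; random lists -0.45 to 0.86), Mef2c (-3.44) being lower. Of macrophage genes 0 of 12 genes were at least 2 times higher and 12 at least 2 times lower (median -9.16; random lists -0.57 to 0.86), and of fibroblast and matrix genes 6 of 27 genes were at least 2 times higher and 10 at least 2 times lower (median -0.43; random lists -0.25 to 0.72), with Mgp (2.69) and Pdgfrb (2.35) higher and Postn (-7.16) and Thy1 (-6.00) lower in C2C12. Genes of the B cell list were lower in C2C12 (0 and 10 of 13; median -5.80), among them Laptm5 (-9.62) and Rac2 (-7.98), which are expressed across white blood cells, and so were MHC class I genes (0 and 7 of 10; -1.95), with Psmb8 (-7.32) and H2-K1 (-2.58). G1/S genes were higher in C2C12 (17 and 0 of 22; median 1.78; random lists -0.18 to 0.80), with Ccne2 (3.71) and Cdc6 (3.40), as were cholesterol genes (12 and 0 of 14; 1.44; random lists -0.34 to 0.88), with Fdft1 (2.40) and Sqle (1.96). Heat shock genes (8 and 2 of 12; 1.15) included Hspb1 (5.43) and Hsph1 (2.39), and Hspa8, which has pseudogenes, at -2.38. The kidney and neural list (11 of 11 higher; 2.55) included the neurofilaments Nefl and Nefm (5.31), and the neuronal list (3 and 2 of 5; 2.56) Stmn2 (5.75) and Tubb3 (4.08). Medians also lay outside the random range for ribosomal protein genes (0.79), nuclear long non-coding RNAs (-1.18), G2/M genes (-0.16) and immediate early genes (-0.69), and within it for the other 7 lists. Cell by cell, each C2C12 cell set beside the summed MEFs, the medians ran from -3.15 to 0.55 for fibroblast and matrix, -1.98 to 3.59 for neuronal, -1.89 to 0.86 for G2/M and -2.99 to 0.07 for nuclear long non-coding genes.

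**Figure D5:**
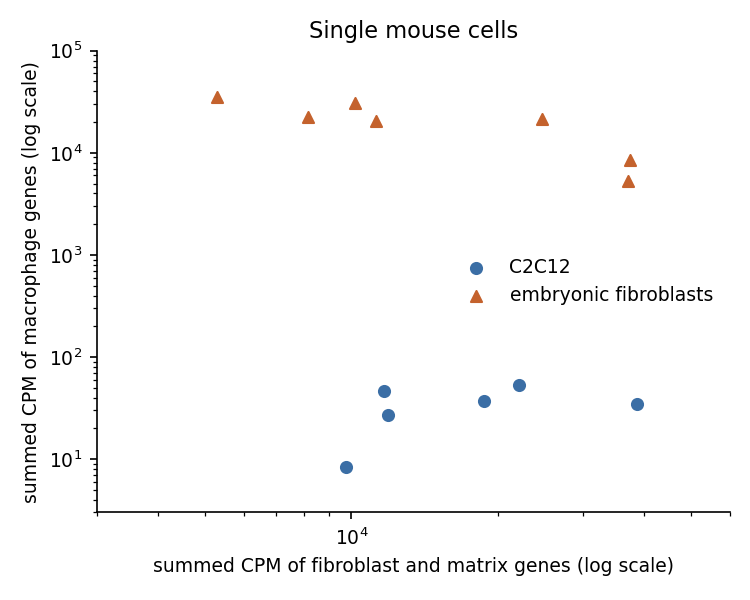
Summed CPM of 12 macrophage genes against summed CPM of fibroblast and matrix genes (both log axes), 1 point per mouse cell. The 7 MEFs lay between 5336 and 34976 CPM of macrophage genes and the 6 C2C12 cells between 8.40 and 52.6, while the fibroblast sums overlapped.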

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

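The tests of explanations and the counts over other splits in this part were chosen only after the results were seen, while the interaction test and the search for libraries far from their group were planned.

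CASC5, PDCD4 and CHMP4B took a larger share of the reads as the input of purified RNA fell. In pools of 100, 50 and 10 cells CASC5 was at 48.8, 50.7 and 74.4 CPM, PDCD4 at 164, 185 and 214 and CHMP4B at 3.21, 3.88 and 3.01. Transcription in HEK293T cells as the source is argued against, since the mean CASC5 level of single Smart-Seq2 cells was 1038 times that of pools of 100 cells of the same line, and the lowest cell of that group had 183 times the level of the highest such pool. In variant 3, where 2 of the 6 cells had 18204 and 171623 CPM, the other 4 had 25.1 to 153.2 CPM, near the 31.3 to 64.6 CPM of the pools. In purified RNA the slope of log10 CASC5 CPM on log10 input was -1.01 over 8 libraries (-1.02 to -0.98 leaving each out), so a fixed amount of template per reaction is a candidate explanation there. A fixed amount in every reaction is argued against for pooled cells, where 10 cells had 1.52 times the level of 100 cells (0.972 to 2.89 between libraries) in place of about 10 times, and 8.64% of the level in 100 pg. Whether there is such a template stays open.

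Lysed cells differed from purified RNA in 7208 of 11487 genes at the higher input and in 2252 of 11671 at the lower. Whether transcript length and GC content are the whole cause cannot be told, since offsets from coarse bins may leave or add differences. With the trend removed 6353 genes were called for 100 cells against 1 ng, where 5% of the genes tested would be 574. Of these, 2072 were higher and 2221 lower in both fits, and 355 were called in the opposite direction. As part of the cause they may contribute, since in the lower-input libraries the partial rank correlation of the log2 fold change with length given GC was -0.46, and with GC given length -0.38. The amount of lysate in the reaction cannot be told apart from the same trend: the log2 fold changes of 10 cells over 100 pg and of 100 over 50 cells, which are other libraries, had a Pearson correlation across genes of 0.255 (Spearman 0.308, 11050 genes), and of 0.114 once the trend was removed, which is between the bounds set for the test. A difference between the cells lysed and the cells that gave the RNA stays open, as untested.

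All 7 MEFs had macrophage transcripts, Lyz2 at 10427 ± 7193 CPM and Fcer1g at 2369 ± 946 CPM per cell; C2C12 cells had reads for 8.83 of the 12 genes on average, and no gene of the list is in another list. Carry-over between wells at the rate seen in C2C12 cells is argued against, since the lowest MEF had 101.4 times the summed level of the highest C2C12 cell, which had 0.256% of the mean of MEFs. Wells with macrophage RNA alone are argued against by the summed fibroblast and matrix genes, whose lowest sum in an MEF was 14.1% of the highest. Over the MEFs Col1a1 ran from 256 to 7776 CPM, Col1a2 from 262 to 3742, Lox from 241 to 8632 and Sparc from 535 to 6440. A well with little fibroblast RNA is therefore not excluded. The MEF highest in macrophage genes (34976 CPM) had the lowest fibroblast sum (5286 CPM), and the MEF lowest in them (5336 CPM) had 37128 CPM. Free RNA of 1 composition in every well cannot be told apart from RNA made in these cells: the share of a macrophage gene in the macrophage sum varied by a median of 5.12 times between MEFs (2.93 to 18.6 over 12 genes), and a spread between single cells cannot be set against technical noise. A mixed culture, or cells with both programs, may also give these values, and neither was tested.

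Of 59 searches for a library far from the others of its group 4 found one, where chance gives about 1 in 20. In variant 3 cell 5 the 100 most abundant genes took 36.6% of the reads, the nearest cell of the group having 20.7%. The same cell had a CASC5 level of 171623 CPM, the nearest having 18204 CPM. Smart-Seq2 HEK293T cell 2 had a mean correlation of 0.580 with the other cells of its group, the nearest cell having 0.703. Variant 2 cell 3 had a mean correlation of 0.655 with the others, the nearest having 0.719.

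The difference between lysed cells and purified RNA itself differed between the inputs in 2188 genes by the interaction test. Of 50 splits of the libraries within source, 1, the real one, gave as many genes, the highest of the others giving 2130. Some of the cell libraries exchanged by these splits resemble each other by number (correlations of 0.15, 0.45 and 0.59), so the splits do not exclude chance. Of the 50, 8 kept the real labels of the cell libraries and gave 1620 to 2188 genes, and the other 42 gave at most 2, so the count rests on the difference between pools of 100 and 10 cells.

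For the tested pairs of groups 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split and the highest other gave 7208 and 0 genes for 100 cells against 1 ng (1 of 10 as large), 2252 and 0 for 10 cells against 100 pg (1 of 10), 3567 and 0 for 100 against 10 cells (1 of 10) and 3 and 0 for 1 ng against 100 pg (1 of 10). For 100 against 50 cells the real split gave 0 genes, so 10 of 10 gave as many, and the split that put HEK_50cells replicate 2 with HEK_100cells replicates 1 and 2 gave 701, which points to a structure of the samples. Numbers 2 and 3 pair these samples, number 1 less clearly, and the 4 splits that part all 3 pairs, the real one included, gave 0 genes; with the number as a block the real split gave 1582.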

How the results depend on the processing

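The alternatives named as added were chosen only after the results were seen, and the others were planned. Of 349 values of comparisons under alternatives 266 were taken as unchanged and 27 reversed. Unchanged means within 1.5-fold of the main count for counts of genes or lists, and a move by less than the spread for other values. For named tested genes 1803 of 1929 values kept their side of the threshold, 118 no longer passed and 8 newly passed. For named single-cell genes and lists 918 of 1056 moved by less than the spread and 138 by more, and none reversed. Where no cause is given below, the cause was not tested. Depth limits the genes seen: thinning to 1.8 M reads lowered them from 14989 to 14262 in 1 ng and from 8675.5 to 8624 in 10 pg. Why simulated changes were not recovered for 10 pg was not tested. Leaving out list members whose file entry names several genes could not change anything, since there were 0.

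With all 6 groups in 1 fit, which pools the spread over inputs, 3849 genes were called for 100 cells against 1 ng (main 7208), 1117 for 10 cells against 100 pg (2252), 1611 for 100 against 10 cells (3567), 11 for 100 against 50 cells (0), 6 for 1 ng against 100 pg (3) and 4298 for 1 ng against 10 pg (2044). With the length and GC trend removed (added) 1374 were called for 10 cells against 100 pg and 41 for 100 against 50 cells. For 100 against 50 cells DESeq2 called 63, no filter 5, the replicate block 1582 and the block with the trend removed (added) 1308. For 100 against 10 cells the block gave 4720. For 1 ng against 100 pg DESeq2 called 25, no filter 5, the block 1, the same libraries without a block (added) 1, and the fit without CASC5, PDCD4 and CHMP4B (added) 0. For 1 ng against 10 pg the stricter filter, which tests fewer genes, gave 959, and the block and the same libraries without it (added) gave 0 and 0, from fewer libraries. The same libraries without a block (added) gave 1285 for 10 cells against 100 pg and 735 for the interaction, which with the block gave 964, again from fewer libraries. With an estimated correlation 0 lists passed in each of the 6 comparisons (main 7, 5, 5, 3, 2 and 3).

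Leaving out each library in turn gave 6335 to 7988 genes for 100 cells against 1 ng, 1252 to 2264 for 10 cells against 100 pg, 2174 to 4608 for 100 against 10 cells, 0 to 43 for 100 against 50 cells, 1 to 2 for 1 ng against 100 pg, 0 to 8516 for 1 ng against 10 pg and 1385 to 2919 for the interaction. Where this left 1 library of 10 pg, that library was assumed to vary like the others.

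For genes detected, 1 ng exceeded 10 pg by 5638 (5426 to 5850 leaving out each library), by 3626.5 at 5 reads, 3684 at RPKM of 1 and 6314 at deposited depth. The difference of 100 cells over 10 cells (17.8 to 153.3 leaving out each library) reversed to -545 at 5 reads and -669 at RPKM of 1, and was 695 at deposited depth. That of 10 cells over 100 pg, 934 (889 to 1024), became 248, 206 and 1099. That of 100 cells over 1 ng, -140 (-180.2 to -108.2), became -521 and -609, and reversed to 351 at deposited depth, where the pools were deeper. For spread, 10 pg exceeded 1 ng by 0.636 (0.631 to 0.688), by 0.465 with 10 CPM added and by 0.568 on RPKM. The difference of 10 over 100 cells ranged from -0.106 to 0.132, reversing without HEK_100cells replicate 3, and that of Smart-Seq2 cells over 10 cells from 0.620 to 1.07, with 0.629 at 10 CPM added and 0.837 on RPKM. Variant 2 over Smart-Seq2, 26.1 genes, reversed to -164 at 5 reads, -209 at RPKM of 1, -32.8 at deposited depth and -50.4 at 2.5 M reads. The correlation of variant 3 cells over Smart-Seq2, 0.000929, reversed to -0.00162 with 10 CPM added. Leaving out each cell of either group in turn (added, except for SMART-Seq cells), SMART-Seq minus Smart-Seq2 ranged from -2799 to -1858 genes and from -0.101 to -0.0221 in correlation. Variant 1 ranged from -73.04 to 286.3 genes and from -0.00459 to 0.0671, variant 2 from -188.7 to 263.9 and from -0.0340 to 0.0445, variant 3 from -3196 to -2510 and from -0.0521 to 0.0195, and variant 4 from -596 to -229 and from -0.0415 to 0.0301. The lowest correlation of each was that without HEK_SS2 cell 2.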

Other observations

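No test of an explanation was made in this part.

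Further lists were summed per mouse cell. Genes of the B cell list, some of which are expressed across white blood cells, were at 150.2 ± 38.4 CPM per C2C12 cell and 3815 ± 1423 CPM per MEF. Neuronal genes were at 576 CPM over the C2C12 cells and 23.9 CPM over the MEFs. Summed endothelial genes were at 8.43 ± 10.7 CPM per C2C12 cell and 11.2 ± 10.2 CPM per MEF, T cell genes at 0.429 ± 0.362 and 2.29 ± 3.87 CPM, and MHC class II genes at 8.53 ± 20.4 and 8.07 ± 15.9 CPM. Epithelial genes were at 76.3 ± 44.8 CPM in C2C12 cells and 7.72 ± 10.9 CPM in MEFs. Contractile genes were at 6542 ± 2066 CPM in C2C12 cells and 4085 ± 1199 CPM in MEFs. Among single macrophage genes the complement components C1qa, C1qb and C1qc were at 710.1 ± 653, 839 ± 757 and 773 ± 635 CPM in MEFs, and each was under 1 CPM in C2C12 cells on average. Col1a1, a collagen chain of fibroblasts, was at 105 ± 202 CPM in C2C12 cells and 2037 ± 2660 CPM in MEFs, and Sparc, a matrix protein, at 2813 ± 1113 and 2479 ± 2148 CPM. Rn45s, the ribosomal RNA precursor, was at 25685 ± 6377 CPM in C2C12 cells and 40123 ± 16254 CPM in MEFs.

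The mouse counterpart of CASC5 was at 66.2 ± 64.7 CPM in C2C12 cells and 54.6 ± 72.4 CPM in MEFs, which are single cells taken through Smart-Seq2, while single HEK293T and DG-75 cells were at 50677 ± 39114 and 44784 ± 13475 CPM. The ratio of CHMP4B to CASC5 was 0.0335 ± 0.00625 in Smart-Seq2 HEK293T cells, 0.0453 ± 0.0140 in DG-75 cells, 0.0393 ± 0.000485 in 10 pg and 0.0415 ± 0.00183 in 1 ng of RNA. The ratio of PDCD4 to CASC5 was 0.182 ± 0.0253, 0.321 ± 0.123, 0.193 ± 0.0304 and 1.65 ± 0.160 in the same groups.

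For 1 ng over 100 pg the rank correlation across genes of the log2 fold change was -0.28 with transcript length and 0.37 with GC content, and for 1 ng over 10 pg it was -0.07 and 0.01.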
